A study of Gracilariopsis lemaneiformis with 12 samples.

How the data were processed

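Thalli of Gracilariopsis lemaneiformis were kept in seawater with antibiotics and then in fresh medium, starved for 7 days, and cultured at 0.5 g per L, 17 °C and 100 µmol photons per m2 per s with 12 h of light a day; part of the medium was renewed every 4 days and nutrients were added every 2 days, per the series description. Total RNA was made into Illumina TruSeq libraries, per the labels' protocols. The 12 samples were grouped by their titles into LCLN, LCHN, HCLN and HCHN, 3 each. The CO2 and nitrate levels behind the letters were read from the crossed design in the series description, since every sample carries the same treatment label.

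The authors deposited a single table of TPM values with 2 decimals for 119261 genes, and each column sums to the same total within rounding. The header line holds 15 cells, 2 of them empty, over rows of 13 cells, so the 12 sample names were matched in order to the 12 value columns. The gene IDs have the form that the de novo assembler Trinity writes; the assembler version and the quantifier are not given in the sources used here. CASAVA 1.7, Bowtie 0.12.2 and the mouse builds mm10 and GRCm38 are named per the submitters' processing notes, and mouse builds do not match a red alga with Trinity gene IDs, so these names were not used. TPM depends on everything else in the library: when an assembly holds transcripts found in some libraries and not in others, the values of all other genes are diluted in the former. An exact 0 in such a table can be a failed estimate, and genes are therefore said to be listed at 0. Of the tested genes, 27.1% share a Trinity component with another tested gene, so reads may be split between copies or fragments of a gene, and single-gene values are uncertain for these. No annotation was used here, so the 25 gene lists drawn up before the data were examined could be matched to no ID and were not tested.

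The design foresaw a count model for counts and, for TPM, limma-trend (limma 3.58.1 in R 4.3.3), which was used. Values were log2(TPM + 1), so a fold change is on that scale and understates the change of low genes. Genes at 1 TPM or more in at least 3 libraries entered (41378), and 1 model with a mean for each group was fitted to all 12 libraries, with no replicate block. The 6 contrasts were HCLN minus LCLN, HCHN minus LCHN, LCHN minus LCLN, HCHN minus HCLN, HCHN minus LCLN, and the difference of the CO2 effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Values per library were compared by exact two-sided permutation tests on means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

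With no names to go by, the rule fixed before the data were examined names the 2 IDs with the largest increase and the 2 with the largest decrease. It was applied to each comparison among called genes with a mean of at least 5 TPM in a group and, except for the interaction, no overlap between the 3 libraries of each group.

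The shared genes (above 0 in all 12 libraries) were defined after the data were seen. They were fitted in the same model after dividing each library by the median ratio of these genes to their geometric means, or after scaling to their total. Alternatives fixed beforehand were median centring, no filter, a pseudocount of 0.1, a log2 fold minimum of 1, only the libraries of a comparison, a replicate block, and leaving out each library in turn.

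The fit was tested on simulated data built from the real group means and the real spread at each CO2 level. The 2 groups of a contrast were set to their average, 200 genes were then changed, and simulated values under 0 were set to 0. With 41378 genes and the nitrate contrast at low CO2, 10% of changes of 1 on the log2 scale and 56% of changes of 2 were recovered, and 605 unchanged genes were called; a fit of that comparison's libraries alone recovered 0% and 0%. In the other single-factor contrasts the figures were 2%, 28% and 51 unchanged genes for CO2 at low nitrate, 1%, 32% and 34 for CO2 at high nitrate, and 1%, 42% and 13 for nitrate at high CO2. In each of these 4 contrasts unchanged genes made up more than 5% of the calls in this single draw. In the nitrate contrasts, whose groups share a spread, the adjusted p so did not hold its nominal rate. In the CO2 contrasts the spread differs between the groups, and setting values under 0 to 0 can shift an unchanged gene. The excess there, also in the fits of own libraries below, does not test the adjusted p. A larger share of changed genes was not simulated. Fits of a comparison's own libraries recovered 6% and 35% for CO2 at low nitrate with 880 unchanged genes called, 2% and 44% for CO2 at high nitrate with 961, and 2% and 50% for nitrate at high CO2 with 3. With the 3928 tested shared genes, recovery of changes of 1 and 2 was 19% and 77% for CO2 at low nitrate, 32% and 88% for CO2 at high nitrate, 19% and 76% for nitrate at low CO2 and 33% and 80% for nitrate at high CO2, with 1, 13, 16 and 26 unchanged genes called, more than 5% of the calls in the last 3. In a further simulation of CO2 at low nitrate the shared genes were diluted as in the real libraries. There 411 of the unchanged shared genes were called on TPM as deposited and 8 after median scaling. Their median log2 change on TPM as deposited was 0.659, whereas that of the real shared genes was -0.58. The simulated shift so has the opposite sign, and the simulation does not show that median scaling corrects the real one.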

Results

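RNA from thalli of the red seaweed Gracilariopsis lemaneiformis, an alga farmed for its agar, was sequenced in 12 libraries. The culture design crossed CO2 with nitrate, and the 12 libraries carry 4 group names with 3 libraries each. They are read here as low CO2 with low nitrate (LCLN), low CO2 with high nitrate (LCHN), high CO2 with low nitrate (HCLN) and high CO2 with high nitrate (HCHN); the concentrations are not given in the sources used here. The file lists 119261 genes of a Trinity assembly, a transcriptome built from the reads themselves, in TPM, the usual share-of-library unit that corrects for transcript length. Because TPM keeps no read total, the depth of each library is unknown, and no counting interval can be given. Gene IDs are not paired with gene names in the file, so genes are named by their assembly IDs and no pathway or gene family could be followed. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between libraries, which may be technical.

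The libraries of the 2 CO2 levels differed first in how many assembled genes they listed. At low CO2 a library listed 62523 ± 9924 genes above 0 (mean ± SD, n = 6), against 11148 ± 6043 at high CO2 (n = 6). Every low-CO2 library listed more genes than every high-CO2 library (exact two-sided permutation test over 924 splits, p = 0.00216, the smallest these splits can give; adjusted p = 0.0162 over 15 tests). By group the means were 55687 ± 2446 genes in LCLN, 69359 ± 10001 in LCHN, 13037 ± 8599 in HCLN and 9259 ± 2579 in HCHN (SD, n = 3 each). With 3 libraries against 3, the exact test cannot go below p = 0.1, which both CO2 contrasts within a nitrate level reached. LCHN against LCLN reached it too, while HCHN against HCLN gave p = 0.6 in the exact test. The spread in HCLN came from replicate 2, which listed 22961 genes, whereas replicates 1 and 3 listed 7820 and 8329.

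A set of 3973 genes lay above 0 in all 12 libraries and is called the shared genes. They held 95.7% ± 5.93 of the TPM at high CO2 and 57.2% ± 10.3 at low CO2 (SD, n = 6 each). This partly restates the difference in genes listed, since the set is bounded by the 4423 genes above 0 in all 6 high-CO2 libraries. In HCLN replicate 2 the genes outside this set held 16.3% of the TPM, against 1.77% and 0.64% in HCLN replicates 1 and 3. In LCHN they held 54.7%, 23.97% and 40.7% of replicates 1, 2 and 3. The 100 most abundant shared genes held 30.3% ± 2.07 of the TPM in LCLN, 44.7% ± 12.0 in LCHN, 73.2% ± 7.38 in HCLN and 69.5% ± 2.64 in HCHN (SD, n = 3). They were ranked by mean TPM over all 12 libraries, which leans on high-CO2 values, so a larger share there is partly built in. The 2973 least abundant shared genes held 8.37% ± 1.00 in LCLN, 4.67% ± 1.24 in LCHN, 5.13% ± 0.28 in HCLN and 7.24% ± 1.57 in HCHN. A further 18139 genes lay above 0 in all 6 low-CO2 libraries and were listed at 0 in all 6 high-CO2 libraries. Of the 41378 genes that passed the filter on low values, 28068 were listed at 0 in all 6 high-CO2 libraries.

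**Figure D1:**
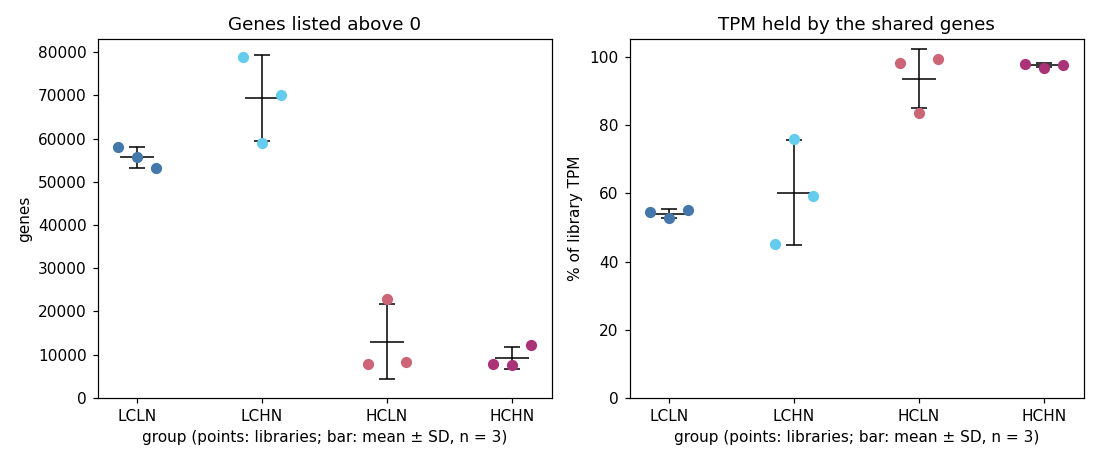
Number of genes above 0 TPM (left) and percent of TPM held by the 3973 shared genes (right) in each library of the 4 groups; points are libraries, the horizontal bar is the group mean and the whiskers are 1 SD (n = 3), which for HCLN pass 100%. The 6 high-CO2 libraries list between 7667 and 22961 genes and the 6 low-CO2 libraries between 53190 and 79009.

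The first comparison asks how the transcriptome at low nitrate differed between high and low CO2. Of 41378 genes tested, 745 were higher and 24090 lower in HCLN than in LCLN (limma-trend, adjusted p under 0.05), and 17263 of the lower genes were listed at 0 in all 3 HCLN libraries. TRINITY_DN1584_c0_g1 rose from 5.70 ± 4.84 TPM to 875 ± 480 TPM (SD, n = 3), a log2 change of 7.14 ± 1.39 (SE; adjusted p = 0.00123). TRINITY_DN33768_c0_g1 rose from 2.72 ± 2.25 TPM to 472 ± 279 TPM, a log2 change of 6.91 ± 1.16 (SE; adjusted p = 0.000505). Among the decreases, TRINITY_DN109130_c0_g1 stood at 5323.31, 8090.97 and 1763.35 TPM in the LCLN libraries and was listed at 0 in the 3 HCLN libraries (adjusted p = 1.11e-07). TRINITY_DN4671_c0_g1 stood at 2972.35, 1236.01 and 1837.16 TPM in LCLN and was listed at 0 in every high-CO2 library (adjusted p = 6.7e-08). Among the 862 tested genes with a mean over 100 TPM across the 12 libraries, of which 76 were listed at 0 in all high-CO2 libraries, 230 were higher and 352 lower. Scaling all genes to the shared genes described above kept most calls lower, with 1164 higher and 19381 lower by their median and 428 and 31662 by their total. Centring each library on the median of all tested genes gave 7248 higher and 3997 lower, but that median was 0 in every high-CO2 library and 1.32 to 1.86 in the low-CO2 libraries on the log2 scale, so centring lowers the low-CO2 values alone.

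Within the shared genes alone, scaled to their median ratio, 993 of 3973 were higher and 985 lower in HCLN. This scaling sets the median change near 0 in every comparison, so the near-even splits it gives here and below come from the scaling and say nothing about the balance of directions. On unscaled TPM the median shared gene had fallen by 0.58 on the log2 scale, and scaling to the shared-gene total instead gave 268 higher and 2558 lower, so which shared genes count as lower depends on the scaling. Of the 100 most abundant shared genes, 69 were higher and 8 lower with the median scaling, and 63 were higher and 15 lower without it. The 2973 least abundant went the other way, with 533 higher and 841 lower with the median scaling. Without it, 237 were higher and 1198 lower among the 2928 of them tested. Ranking by mean TPM over all 12 libraries favours shared genes high at high CO2, so the excess of higher genes among the 100 is partly built in. A set defined by a value above 0 in all libraries leaves out genes that fell to 0, and so understates decreases.

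At high nitrate the same CO2 contrast gave 1892 genes higher and 19797 lower in HCHN than in LCHN, with 19199 of the lower genes listed at 0 in the 3 HCHN libraries. TRINITY_DN21155_c0_g1 rose from 0.53 ± 0.366 TPM to 536 ± 304 TPM (SD, n = 3), a log2 change of 8.25 ± 0.57 (SE; limma adjusted p = 2.25e-06). TRINITY_DN37682_c0_g1 rose from 2.19 ± 1.78 TPM to 541 ± 158 TPM, a log2 change of 7.55 ± 0.56 (SE; adjusted p = 3.62e-06). TRINITY_DN109130_c0_g1 fell again, from 7086.1, 11146.12 and 9312.72 TPM in LCHN to 0, 0.23 and 0 TPM in HCHN (adjusted p = 9.24e-08). TRINITY_DN2239_c0_g2 stood at 6145.42, 1552.87 and 10158.25 TPM in LCHN and was listed at 0 in HCHN (adjusted p = 2.16e-06). Scaling all genes to the shared-gene median gave 1221 higher and 24807 lower, to their total 1119 and 27118, and centring on the median of all tested genes, which was 0 at high CO2, 6182 and 3848. Shared genes scaled to their median gave 941 higher and 921 lower; scaled to their total they gave 835 and 673, and without rescaling 1512 and 275, where the median shared gene stood 0.62 higher on the log2 scale. Of the 100 most abundant shared genes 27 were higher and 17 lower with the median scaling, and 47 were higher and 11 lower without it. The 2973 least abundant gave 611 higher and 702 lower with the median scaling, and the limit of the ranking given above holds here too. The 862 tested genes with a mean over 100 TPM gave 333 higher and 254 lower. The difference from low nitrate was not tested for these sets as a whole.

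The CO2 effects at the 2 nitrate levels, which share no library, overlapped. Both contrasts use the same spread per gene from the fit of all 12 libraries, so even unrelated effects could share more genes than independent lists. In the shared genes, 621 were higher at both nitrate levels, where independent lists would share 235.2, and 563 were lower at both, against 228.3. Another 23 of the genes higher at low nitrate were lower at high nitrate, and 15 went the other way. The log2 changes at the 2 nitrate levels correlated at r = 0.698 across the 3973 genes, which are not independent replicates. Over the 13310 tested genes above 0 in a high-CO2 library, 557 were higher at both levels (105.9 for independent lists) and 2925 lower at both (1894.2). The other 28068 cannot be called higher, and bring the genes lower at both to 13381. The genes higher at both levels included TRINITY_DN1584_c0_g1, whose mean was 87.6 ± 76.3 TPM in LCHN and 4489 ± 2983 TPM in HCHN (SD, n = 3).

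**Figure D2:**
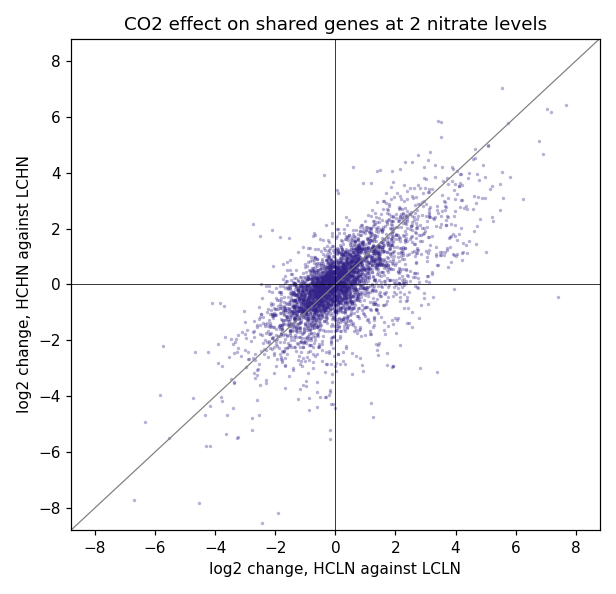
Log2 change of each of the 3973 shared genes with high CO2 at low nitrate (HCLN against LCLN, horizontal) and at high nitrate (HCHN against LCHN, vertical), after scaling each library to the shared-gene median; each point is a gene and the grey line marks equal changes. The changes correlate at r = 0.698 across genes.

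The nitrate contrast at low CO2 gave 4554 genes higher and 10326 lower in LCHN than in LCLN. TRINITY_DN13320_c0_g1 was listed at 0 in the 3 LCLN libraries and stood at 71.47, 55.12 and 59.08 TPM in LCHN (limma adjusted p = 5.29e-06). TRINITY_DN12902_c0_g1 stood at 2.4, 1.55 and 0 TPM in LCLN and at 793.72, 76.48 and 108.89 TPM in LCHN, a log2 change of 6.53 ± 0.75 (SE; adjusted p = 0.000295). TRINITY_DN84217_c0_g1 stood at 134.22, 31.99 and 42.84 TPM in LCLN and was listed at 0 in LCHN (adjusted p = 0.000152). TRINITY_DN4498_c0_g1 fell from 1149 ± 666 TPM to 21.4 ± 27.3 TPM (SD, n = 3), a log2 change of -6.27 ± 2.24 (SE; adjusted p = 0.0481), and lost this call when any 1 of the 6 libraries was left out. Among the high-CO2 libraries it was listed above 0 in HCLN replicate 2 alone, at 1606.63 TPM. It so belongs to a block of genes in HCLN replicate 2 described in a later section. That block as a whole held 10.2%, 4.24% and 10% of the TPM in LCLN and 2.87%, 0.29% and 2.03% in LCHN.

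These nitrate counts come from the fit of all 4 groups: a fit of the 6 low-CO2 libraries alone called 3 genes, with 13262 at an unadjusted p under 0.05; there TRINITY_DN12902_c0_g1 had an adjusted p of 0.0741 and TRINITY_DN84217_c0_g1 of 0.063, while TRINITY_DN13320_c0_g1 was called. Leaving out LCLN replicate 3 gave 7964 genes (3630 higher, 4334 lower) and leaving out LCHN replicate 1 gave 9663 (1655 higher, 8008 lower); without LCHN replicates 2 and 3 the higher genes numbered 3035 and 2685. The balance of directions depended on scaling: median centring gave 5380 higher and 3616 lower and scaling to the shared-gene median 6183 and 1285, whereas scaling to the shared-gene total gave 5818 and 12776. Shared genes scaled to their median gave 328 higher and 305 lower; their total gave 87 and 2162, and unscaled TPM 85 and 1724, where the median shared gene had fallen by 0.81. Leaving out LCLN replicates 1, 2 and 3 changed the 633 shared calls to 368, 202 and 346, and leaving out LCHN replicates 1 and 2 to 187 and 368.

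At high CO2 the nitrate contrast called 2 of 41378 genes (limma-trend), with 960 at an unadjusted p under 0.05. The 28068 genes listed at 0 in all high-CO2 libraries have no difference here and cannot be called. The 960 so lay among the other 13310 tested genes. TRINITY_DN690_c0_g2 stood at 7.68, 17.14 and 10.1 TPM in HCLN and was listed at 0 in every other group (adjusted p = 0.00658). TRINITY_DN16496_c0_g1 stood at 3.56, 3.44 and 2.99 TPM in HCHN and was listed at 0 in every other group (adjusted p = 0.00721); it lies under the minimum of 5 TPM for named genes and was chosen after its values were seen. Neither gene was called in a fit of the 6 high-CO2 libraries alone, where both had an adjusted p of 0.485. TRINITY_DN690_c0_g2 had adjusted p-values of 0.0997, 0.101 and 0.0985 without HCHN replicates 1, 2 and 3, and TRINITY_DN16496_c0_g1 of 0.301, 0.107 and 0.151 without HCLN replicates 1, 2 and 3; with a library of its own group left out, each fell under the filter on low values. None of the 3973 shared genes was called in the limma fit on median-scaled values, with 328 at an unadjusted p under 0.05. Leaving out HCHN replicate 3 gave 5 shared calls, and leaving out any 1 of the 6 libraries gave 0 calls over all tested genes.

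The combined contrast, HCHN against LCLN, gave 1242 genes higher and 23844 lower, with 22441 of the lower genes listed at 0 in HCHN. TRINITY_DN1584_c0_g1 rose to 4489 ± 2983 TPM from 5.70 ± 4.84 TPM (SD, n = 3), a log2 change of 9.43 ± 1.39 (SE; limma adjusted p = 0.000227). TRINITY_DN21155_c0_g1 rose to 536 ± 304 TPM from 0.13, 0.1 and 0 TPM, a log2 change of 8.73 ± 0.57 (SE; adjusted p = 1.43e-06). TRINITY_DN95585_c0_g1 fell from 6532 ± 3267 TPM to 0, 0.21 and 0 TPM (adjusted p = 2e-04), and in HCLN it stood at 0, 448.35 and 5.19 TPM. TRINITY_DN109130_c0_g1 was again among the largest decreases (adjusted p = 1.19e-07). Scaling all genes to the shared-gene median gave 1310 higher and 20144 lower, to their total 753 and 31490, and centring on the median of all tested genes, which was 0 at high CO2, 8482 and 6516. Shared genes scaled to their median gave 1000 higher and 981 lower, and scaled to their total 412 and 2164.

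The interaction tests whether the CO2 effect differed between the nitrate levels. It was called for 4130 genes, of which 2167 had a more positive CO2 effect at high nitrate and 1963 a more negative one. Of these, 2793 (1108 more positive, 1685 more negative) were listed at 0 in all high-CO2 libraries, where the interaction equals the nitrate effect at low CO2 with its sign turned, and all 2793 were also called in that nitrate contrast. The other 1337 comprised 1059 more positive and 278 more negative. TRINITY_DN85210_c0_g1 averaged 87.5 ± 70.9 TPM in LCLN and 7.96 ± 6.07 TPM in HCLN, against 24.03 ± 34.5 TPM in LCHN and 105 ± 75.8 TPM in HCHN (SD, n = 3), an interaction of 6.18 ± 1.53 on the log2 scale (SE; limma adjusted p = 0.03). TRINITY_DN84217_c0_g1, listed above 0 in LCLN alone and so among the 2793, had an interaction of 5.86 ± 0.64 (SE; adjusted p = 0.00505). TRINITY_DN33768_c0_g1, which rose with CO2 at low nitrate, averaged 404 ± 355 TPM in LCHN and 250 ± 128 TPM in HCHN, an interaction of -6.62 ± 1.64 (SE; adjusted p = 0.0297). TRINITY_DN3274_c0_g1 stood at 53.98, 261.66 and 17.29 TPM in LCHN and 0, 81.01 and 0 TPM in HCLN, and was at most 1.94 TPM in the other libraries, an interaction of -7.60 ± 2.10 (SE; adjusted p = 0.044).

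The calls of 3 of these genes were lost when some libraries were left out, and under some other settings. TRINITY_DN85210_c0_g1 lost it without LCLN replicate 3, LCHN replicates 1 and 3, HCLN replicates 1 and 3, and HCHN replicates 1 and 2 (adjusted p from 0.0625 to 0.0829). TRINITY_DN33768_c0_g1 lost it without LCLN replicates 2 and 3, LCHN replicate 1, HCLN replicates 1 and 3, and HCHN replicates 1 and 2 (0.0591 to 0.0811). TRINITY_DN3274_c0_g1 lost it without any 1 library other than HCLN replicate 2 (0.0509 to 0.099). With no filter on low values the 3 genes had limma adjusted p-values of 0.112, 0.111 and 0.141 in this order. TRINITY_DN85210_c0_g1 also lost its call with all genes scaled to the shared-gene median (0.0562). The replicate block ended that of TRINITY_DN33768_c0_g1 (0.0549), and a pseudocount of 0.1 that of TRINITY_DN3274_c0_g1 (0.0612). The count of interactions moved when most single libraries were left out: to 7080 without LCLN replicate 1, 1978 without LCLN replicate 3, 1758 and 1906 without LCHN replicates 1 and 3, 1331, 1603 and 1304 without HCLN replicates 1, 2 and 3, and 1267, 1326 and 2623 without HCHN replicates 1, 2 and 3. Testing all 116688 genes above 0 gave 244, and scaling to the shared-gene median turned the split to 429 more positive and 2363 more negative, whereas scaling to the total gave 2601 and 1791. Without LCHN replicates 1 and 3 the more negative calls fell to 211 and 341, beside 1547 and 1565 more positive. Shared genes scaled to their median gave 74 and 104, and scaled to their total 2178 and 42. Their 178 calls became 14, 21 and 64 without LCLN replicates 1, 2 and 3, 14, 62 and 333 without LCHN replicates 1, 2 and 3, 273, 29 and 33 without HCLN replicates 1, 2 and 3, and 51 and 103 without HCHN replicates 1 and 2.

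**Figure D3:**
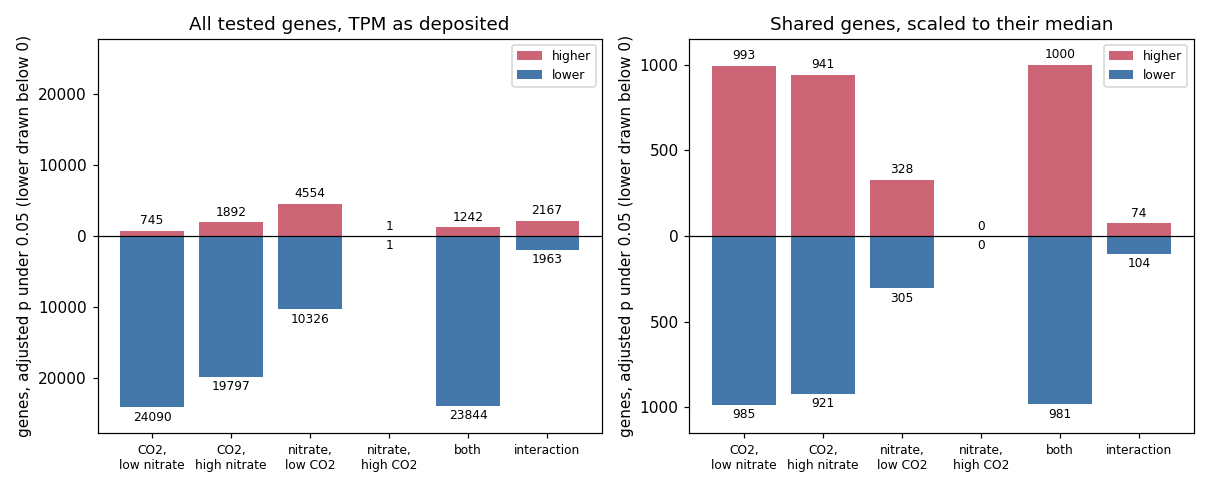
Number of genes past an adjusted p of 0.05 (limma-trend) in each comparison, higher drawn above 0 and lower below it, for all 41378 tested genes on TPM as deposited (left) and for the 3973 shared genes scaled to their median (right); for the interaction, higher means a more positive CO2 effect at high nitrate. High CO2 at low nitrate gives 745 higher and 24090 lower on the left, and 993 and 985 on the right, where the scaling sets the near-even split.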

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

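The tests on the listing of genes, on the block of genes in HCLN replicate 2, on the spread behind the nitrate calls, on regroupings for the interaction and on the second block at minimum TPM values were chosen only after the result was seen. The other splits, the test on the 0.10 threshold and the test on the second block as a whole were not. The shared genes, whose splits are among these, were themselves defined after the data were seen.

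The CO2 effect differed between the nitrate levels, by the interaction term, for 4130 genes, and for 178 of the shared genes scaled to their median. For 2793 of the 4130, listed at 0 in all high-CO2 libraries, the term repeats the nitrate effect at low CO2 with its sign turned, as for TRINITY_DN84217_c0_g1 and TRINITY_DN13320_c0_g1. Labels were regrouped in 3 ways, and the one given first was chosen last, after the values of the others were seen. With the low-CO2 labels kept, the 20 arrangements of the nitrate labels at high CO2 are too few for a share under 0.05: 1 of 20 gave as many as the real 4130 (others 2441 to 4120), and for the shared genes 7 of 20 gave as many as the real 178 (highest other 426). Such arrangements cannot move the fold of a gene listed at 0 in all high-CO2 libraries, and these genes gave 2215 to 2785 calls in the others; genes above 0 in a high-CO2 library gave 226 to 1335, against the real 1337. With labels regrouped within both CO2 levels (100 of 200 arrangements), 1 of 100 gave as many (highest other 4120), and 2 of 100 for the shared genes (highest other 263); with labels regrouped over all 12 libraries, 2 of 100 gave as many (highest other 9303), and 4 of 100 for the shared genes (highest other 934). The arrangements with 9303 and 934 calls set groups of mostly low-CO2 libraries against groups of mostly high-CO2 libraries. Their contrast so largely took in the difference between the CO2 levels. In all 3 ways an arrangement can put libraries that differ in nitrate into a group. Regrouping over all 12 libraries also mixes CO2 levels, and none of the 3 is used to exclude chance. The 10 splits of 6 libraries are too few for a share under 0.05 in the other comparisons. Every split but the real one also mixes the 2 compared levels within each group. A large difference between the levels so widens the spread and lowers the calls, and low counts in those splits are no support for the real counts. As many calls came from 1 of 10 splits for CO2 at low nitrate (24835, highest other 0), CO2 at high nitrate (21689, highest other 0), nitrate at low CO2 (14880, highest other 1219) and both together (25086, highest other 0). For nitrate at high CO2 as many came from 10 of 10 (2, highest other 26). In the shared genes it was 1 of 10 for CO2 at low nitrate (1978, highest other 0), CO2 at high nitrate (1862, highest other 0), nitrate at low CO2 (633, highest other 20) and both together (1981, highest other 1), and 10 of 10 for nitrate at high CO2 (0, highest other 2).

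Among the named genes the interaction was past the threshold for TRINITY_DN33768_c0_g1 (-6.62), TRINITY_DN12902_c0_g1 (-6.61), TRINITY_DN13320_c0_g1 (-5.97), TRINITY_DN84217_c0_g1 (5.86), TRINITY_DN690_c0_g2 (-3.59), TRINITY_DN16496_c0_g1 (2.11), TRINITY_DN85210_c0_g1 (6.18) and TRINITY_DN3274_c0_g1 (-7.60), all on the log2 scale. Apart from TRINITY_DN33768_c0_g1 and TRINITY_DN85210_c0_g1, each has libraries listed at 0 in at least 2 groups, so these values depend on the pseudocount. No test of a single outlying library was run, as each group holds 3.

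The first pattern is that low-CO2 libraries listed several times as many genes as high-CO2 libraries. Lower depth at high CO2 is argued against for 33 genes that had at least 100 TPM in every low-CO2 library and were listed at 0 in all 6 high-CO2 libraries. Each high-CO2 library nevertheless listed between 1131 and 3946 genes at values under 1 TPM. For most of the pattern depth stays open. Of the 28068 tested genes listed at 0 in all high-CO2 libraries, 26817 had a mean under 10 TPM over all 12 libraries. This mean takes in the 6 values of 0 at high CO2. The mean of such a gene over the low-CO2 libraries alone is higher and can pass 10 TPM. Scaling to a fixed TPM total is argued against by 5299 genes at 1 TPM or more in every low-CO2 library and listed at 0 in all high-CO2 libraries: a common factor would have to exceed 200-fold to give a 0 at 2 decimals, and the shared-gene medians of the libraries differ by at most 2.65-fold. RNA of other organisms living on the thalli at low CO2 stays open: a block of genes that moved together, described next, held 10.85% of the TPM outside the shared genes on average over the low-CO2 libraries (1.22% to 22.34%), which neither needs nor excludes such a source. A response of the alga to CO2, and a difference in how the libraries of each CO2 level were made, which no label records, also stay open and were not tested apart.

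The second pattern is a block of 1734 genes at 5 TPM or more in HCLN replicate 2, under 0.5 TPM in the other 5 high-CO2 libraries and above 0 in LCLN replicate 2. At these low values HCLN replicate 3 listed 1152 of them above 0, with 0.0149% of its TPM. HCHN replicate 1 listed 120, and HCLN replicate 1 and HCHN replicates 2 and 3 listed 5, 13 and 8. Carry-over from a low-CO2 library is argued against, because of 109 genes at 50 TPM or more in every low-CO2 library and under 0.5 TPM in the other high-CO2 libraries, 5.5% were above 0 in HCLN replicate 2. A candidate explanation is an RNA source present in varying amount: over the 10 pairs of the 5 low-CO2 libraries not used to pick the block, the spread (IQR) of the log2 ratio over its genes was 0.42 to 0.907 of that of shared genes of like TPM. The block held 10.2%, 4.24% and 10% of the TPM in LCLN and 2.87%, 0.29% and 2.03% in LCHN; the 9.8-fold range within LCHN is too wide for an even response and not wide enough to exclude a response to the group. A second set of 4333 genes was listed above 0 in HCLN replicate 2 and HCHN replicate 3 alone, with 3.48% and 0.77% of their TPM, and there the IQR was 1.25 times that of shared genes of like TPM (1.12 to 2.55 times over genes at or above 0.5 to 5 TPM in both), which goes against a single source in a fixed mix but rests on 1 pair of libraries.

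The third pattern is that nitrate at low CO2 called 14880 genes with the spread of all groups and 3 with that of its own libraries. In simulated data with 200 of 41378 genes changed, a fit of those 6 libraries recovered no changed gene. The real fit had 13262 genes at an unadjusted p under 0.05, and the adjusted p depends on how many genes change. The simulation so cannot tell how many calls these data should keep. The loss of calls by itself does not show where the spread came from. For the 5309 calls on genes above 0 in a high-CO2 library, the median SD at high CO2 was 0.764 of that at low CO2, so a lower spread at high CO2 may add to these calls, and the share it adds was not measured. For the 28068 genes listed at 0 in all high-CO2 libraries, the median SD was 0.756 at low and 0 at high CO2. The fit of all groups pools both, so for these genes the zeros put its spread below that of the low-CO2 libraries. How much of their drop from 9571 calls to 1 came from this, and how much from fewer libraries, was not measured. In simulated data with all tested genes, the fit of all groups called more unchanged genes here than in any other single-factor contrast. The 14880 calls may so include an excess of unchanged genes. P-values crowded at the threshold may account for the size of the drop: at an adjusted p under 0.10 the fit of its own libraries called 9451 genes, so the count of 3 does not mean that few genes moved.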

How the results depend on the processing

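Scaling to the shared genes, the filter within a comparison, the block within a comparison and all fits of the shared genes were chosen after seeing the data. Counts moved by more than 1.5 times as follows; except where the setting's construction is named, the cause was not tested. Median centring gave 11245 genes for CO2 at low nitrate, 10030 for CO2 at high nitrate, 8996 for nitrate at low CO2 and 14998 for both together, of which 5190, 5859, 8170 and 8343 were also called on TPM as deposited, and more were higher than lower in each; it subtracts a median of all tested genes, most of which are at 0 at high CO2. Filtering within the comparison gave 14320 genes for CO2 at high nitrate with fewer genes tested (17148). Nitrate at low CO2 gave 7468 after scaling to the shared-gene median, 3 in the fit of its own libraries, 3 with the filter within them, and 7964 to 13661 with a library left out. Nitrate at high CO2 gave 1 with no filter, 5 with a pseudocount of 0.1, 0 in the fit of its own libraries, 0 with the filter within them, and 0 to 0 with a library left out. The interaction gave 244 with no filter and 1267 to 7080 with a library left out. Shared genes changed by nitrate at low CO2 numbered 2249 scaled to their total, 1809 without rescaling and 187 to 800 with a library left out; at high CO2, 0 to 5. Shared-gene interactions numbered 2220 scaled to their total, 1968 without rescaling and 14 to 333 with a library left out. No value of a named gene changed sign; over genes and settings the call was lost 17 times and kept 89 times under planned settings, lost 10 and kept 70 under added ones, and lost 37 and kept 104 with a library left out. A gene above the filter in 3 libraries alone, such as TRINITY_DN13320_c0_g1, has no value without 1 of them.

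Over all groups the replicate numbers did not pair the libraries. Of 18 same-number pairs across groups 2 had deviations correlating over 0.1 (range -0.362 to 0.255), and 2 libraries correlated best with their own number. The 2 pairs over 0.1 were LCLN with LCHN, at 0.211 for replicate 1 and 0.255 for replicate 2, with 0.064 for replicate 3. Pairs of unlike number between LCLN and LCHN lay between -0.292 and 0.09. Whether the numbers pair the libraries at low CO2 so stays open. With the replicate block, nitrate at high CO2 gave 0 genes, the interaction 2597 and the shared-gene interaction 49, and nitrate at low CO2 gave 7784 in the fit of its own libraries, where the 4 genes named for this contrast all had an adjusted p of 0.0306; the other counts stayed within 1.5 times. Count models, voom and count-based size factors need counts and were not run, and the gene list tests were not run for lack of annotation. Depth is unknown, so its effect on low genes cannot be bounded.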

Other observations

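Among the 100 most abundant shared genes, the pair with the steadiest ratio was TRINITY_DN21002_c2_g1 and TRINITY_DN2355_c1_g1, chosen after its values were seen. The ratio of the former to the latter lay between 2.25 and 2.40 in all 12 libraries, while TRINITY_DN21002_c2_g1 itself ranged from 7465 to 104922 TPM and TRINITY_DN2355_c1_g1 from 3114 to 45174 TPM. The SD of their log2 ratio was 0.0275, the lowest of 4950 pairs, whose median was 1.49. TRINITY_DN13396_c0_g7 followed both, with TRINITY_DN2355_c1_g1 at 19.0 to 21.2 times its level. The 3 IDs belong to different Trinity components.

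Nitrate effects at low and at high CO2, which share no library, correlated at r = -0.208 across the 3973 shared genes after median scaling. On TPM as deposited they correlated at 0.341 over the 13310 tested genes above 0 in a high-CO2 library. The CO2 effects at the 2 nitrate levels correlated at 0.698 and 0.778 in these 2 sets. Genes are not independent replicates, and no test was run on the difference. Offsets between kinds of genes enter the 0.341. On TPM as deposited the median nitrate changes at low and high CO2 were -0.809 and 0.446 for the tested shared genes. For genes above 0 at both CO2 levels but not in all libraries they were -1.28 and -0.495.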
